A study of Rattus norvegicus with 6 samples.

How the data were processed

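The data are 6 Affymetrix 3' expression arrays of LN4D6 rat mammary tumour cells, 3 untransfected and 3 transfected with CREB3L1. Per the labels' protocols, total RNA was extracted with a Qiagen kit and labelled with biotin by the 3' IVT Express kit. The values are the authors' deposited log2 expression values, made with RMA in Partek 6.6, per the submitters' processing notes. The log base and the probe-level settings for background and GC content are not given in the sources used here. The deposited values run from 0.27 to 16.9 with array medians of 2.97 to 3.06, the range of log2 intensities, and were taken as log2. Sorted values differed between arrays by up to 0.264 from their mean, so the table was close to quantile normalised but not exactly so. The value table was used as deposited, and scanner files were not used here.

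Groups were taken from the label that states what each sample was transfected with. The labels give no replicate numbers shared between groups, so replicates were numbered in deposit order and no pairing was used. Nothing in the labels says that the arrays came from separate cultures, so p-values measure the spread between these samples only, which may be technical. The number of arrays, 3 per group, limits the precision. No 2 arrays were identical, with at most 10 probe sets exactly equal, to the last deposited digit, between any 2 of them.

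Of 31099 probe sets, 57 controls were set aside and 31042 tested. Gene symbols came from GEO's platform annotation, which can be old, checked against the RefSeq gene table of assembly GRCr8, and 0 symbols changed in that update. 20826 probe sets had 1 gene symbol, 436 had several and 9780 were not listed with a gene, and only those with 1 symbol were given a name. Each of 14217 genes was represented by its probe set with the highest mean over the 6 arrays, and disagreeing probe sets of named genes past the threshold are given beside them. The table holds no detection calls. The background level was to be the 95th percentile of olfactory receptor probe sets or, with fewer than 20 of them named, a log2 value of 5. Only 6 were named, so 5 was used. Where 1 group's mean was below it, a fold is the bright group's mean against that level. No fold is given where both were below it.

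The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group, eBayes without trend, two-sided) on all 6 arrays, with Benjamini-Hochberg adjustment over the 31042 probe sets and a threshold of 0.05. The design, the alternatives, the rule for named genes and the gene lists were fixed before the data were examined. Named genes are Creb3l1, the 15 highest and 15 lowest log2 differences among representatives past the threshold with non-overlapping groups, a higher group mean above background and an official symbol, up to 4 members past the threshold from each list (or the 2 with the smallest p where none passed), and Gapdh and Actb as controls. Gapdh and Actb had no probe set with that single symbol and were read from their 3' control probe sets. 24 lists were fixed, covering the CREB3 family, pathways, cell type markers and control genes. For each, members past the threshold were counted over all probe sets and adjusted over the list alone. Lists with 5 or more measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, each adjusted over the lists.

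The fit was tested on simulated data for 31042 probe sets with the means and spreads of this comparison, with 50 changed probe sets at each size. It recovered 50% of log2 changes of 0.5, 88% of changes of 1, 88% of changes of 2 and 100% of changes of 4, with 6 false calls in all. The simulated noise was independent between probe sets and equal in spread on all arrays. In the data, CREB3L1 replicate 3 differed from CREB3L1 replicates 1 and 2 with an SD of 0.60 and 0.61. Between replicates 1 and 2 the SD was 0.14. The simulated rates may therefore not hold for this comparison.

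Alternatives were quantile normalisation of the table, centring on array medians, leaving out probe sets below background in both groups, eBayes with a mean-variance trend or robust, an ordinary test without moderation, leaving out each array in turn, the mean of all probe sets of a gene, and the other set tests. Weights per array were added after the data were seen, as was the choice to give values without CREB3L1 replicate 3 beside the others. Array quality was read from the 3' and 5' control probe sets of Gapdh, beta-actin and the spiked-in dap RNA. For gene neighbours, 7630 genes with a representative above background were put in the chromosome order of assembly GRCr8. Running medians over 25 genes were searched in 4 arrays, tried on the pair left out (replicate 3 of each group), and compared with 1000 permutations of the gene order. A run takes in every gene of its windows, and windows up to 25 genes apart were joined. Genes at the ends of a run or between its windows therefore need not share its direction. The order serves only to find neighbours, and the scan was chosen after a first look at the data.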

Results

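Transcript levels were measured in LN4D6 cells, a rat mammary tumour line, in 3 untransfected samples and 3 samples transfected with CREB3L1. CREB3L1 is a transcription factor held in the membrane of the endoplasmic reticulum and released by proteolysis. Total RNA of each sample was labelled with biotin and hybridised to an Affymetrix 3' expression array of 31099 probe sets, and the values are log2 RMA expression values. The single comparison of the design, CREB3L1 against untransfected cells, asks which transcripts differ after transfection. Differences are given as CREB3L1 minus untransfected on the log2 scale with the standard error, from limma with Benjamini-Hochberg adjustment, and levels as mean ± SD with n = 3 per group. A log2 value of 5 served as the background level, and 37.95% to 38.59% of the tested probe sets lay at or above it on each array. A fold against a group whose mean lay below that level is a lower bound, computed against the level.

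Of the 6 arrays, CREB3L1 replicate 3 stood apart. Its Pearson correlation with the other arrays across probe sets, which are not independent replicates, was 0.984 to 0.989, against 0.996 to 0.999 among the other 5. The 3' probe set of Gapdh exceeded the 5' probe set by 4.77 on this array and differed by -0.16 to -0.10 on the others, and for beta-actin the gap was 7.44 against 2.35 to 3.41. Results are given with all 6 arrays, as planned. Leaving out each array in turn was planned too, and giving values without this one beside the others was chosen after the data were seen.

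**Figure D1:**
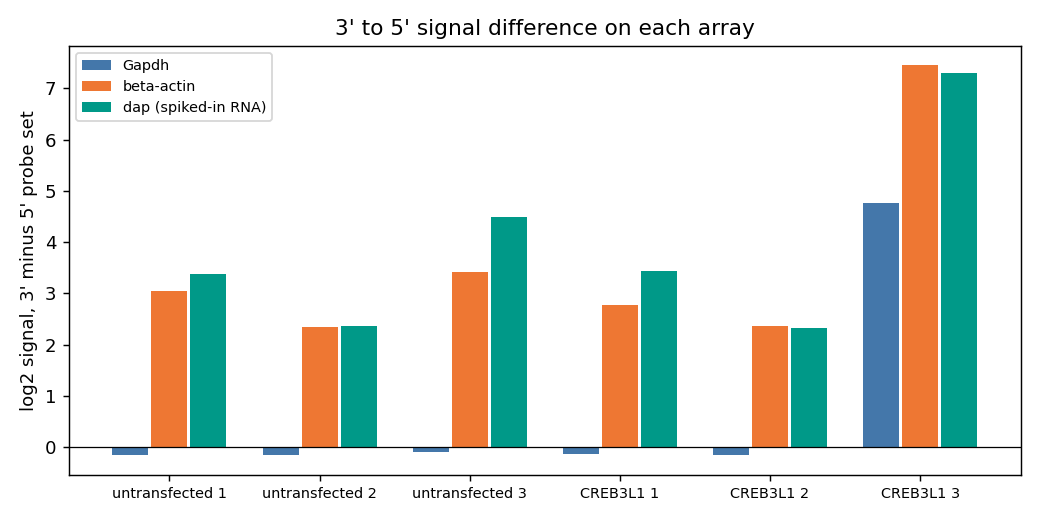
Log2 signal of the 3' probe set minus that of the 5' probe set on each of the 6 arrays, for the Gapdh and beta-actin transcripts and for the spiked-in dap RNA. CREB3L1 replicate 3 shows the widest gap for all 3 RNAs, with 4.77 for Gapdh.

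The transfected gene itself was read by 1 probe set at 3.36 ± 0.02 in untransfected and 3.39 ± 0.03 in CREB3L1 cells, a difference of 0.02 ± 0.03 (adjusted p = 0.9998). Both groups lay below the background level. The species and 3' end of the construct are not given in the sources used here, and a rat 3' probe set may not read it, so this value checks neither the labels nor the transfection.

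Of the 15 genes with the lowest log2 differences, 12 were below background in the CREB3L1 cells. The ranking takes values below background as they are, which favours such genes, so it does not order the true falls. Anp32a, which encodes an inhibitor of protein phosphatase 2A, went from 11.84 ± 0.39 to 3.85 ± 0.67, at least 115-fold lower (adjusted p = 0.00205). Fgfbp1, whose product releases fibroblast growth factors from the matrix, went from 11.32 ± 0.05 to 4.90 ± 0.24, at least 80.1-fold lower (adjusted p = 8.13e-05). Car3, a carbonic anhydrase, fell from 15.05 ± 0.12 to 7.96 ± 1.01, a difference of -7.09 ± 0.51 (adjusted p = 0.00632). The fatty acid binding protein genes Fabp5 and Fabp4 fell by at least 11.5-fold and at least 16.6-fold (adjusted p = 6.37e-05 and 1.76e-04).

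Further falls reached genes of several kinds. Hpgds and Ptges, synthases of prostaglandins D and E, were at least 18.1-fold and at least 8.98-fold lower. Aldh1a1, a retinaldehyde dehydrogenase, was at least 7.67-fold lower, and Spink5, a serine protease inhibitor, at least 15.6-fold lower, with all 3 of its probe sets falling. The copper-dependent ferroxidase gene Heph fell by 5.06 ± 0.37 and the monooxygenase gene Moxd1 by 6.12 ± 0.16. Bend4 was at least 19.5-fold lower and Inhca at least 6.38-fold lower. Prps2, which encodes a phosphoribosyl pyrophosphate synthetase, and Arhgap6 were at least 16.3-fold and at least 12.5-fold lower. Both lie in a run of 95 neighbouring measured genes on the X chromosome whose median difference, relative to all genes, was -0.44. Of the 3 Prps2 probe sets, 1 was below background in both groups and showed no difference (-0.03). A second Car3 probe set went from 11.46 to below background (adjusted p = 6.37e-05), and a second Inhca probe set lay below background in both groups (-0.06).

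Among the 15 genes with the highest log2 differences, Slc10a2, the bile acid transporter of the ileum, went from 2.96 ± 0.11, below background, to 6.10 ± 0.48, at least 2.14-fold higher (adjusted p = 0.00836). Prl8a9, a member of the rodent prolactin family, rose from 10.06 ± 0.14 to 12.95 ± 0.10, which is 7.40-fold (adjusted p = 4.37e-04). Slc17a6, a vesicular glutamate transporter, rose 6.14-fold, Jam3, a junctional adhesion molecule, 5.42-fold, and Mmrn2, a matrix glycoprotein known from endothelium, 4.92-fold (adjusted p = 0.00268, 0.0103 and 0.00915). Nap1l2 rose by 2.06 ± 0.26, the imprinted gene Peg12 rose 4.01-fold, and Sprr1a, a component of the cornified envelope, rose by 1.81 ± 0.23. Apln, which encodes the peptide ligand apelin, rose by 1.92 ± 0.18 and by 2.62 on a second probe set. The second Camkk2 probe set, below background in both groups, gave 0.51 ± 0.27. Rises of 1.65 ± 0.11 in the adenylyl cyclase gene Adcy8, 1.58 ± 0.07 in the calmodulin-dependent kinase kinase gene Camkk2 and 1.57 ± 0.16 in the cytokine gene Tslp followed. The palmitoyltransferase gene Zdhhc9 rose by 1.55 ± 0.21, C8h15orf39 by 1.27 ± 0.10 and Mlec, which encodes a lectin of the endoplasmic reticulum, by 1.31 ± 0.11. The second Mlec probe set gave 0.57 ± 0.72 and did not pass the test, and the mean of both gave an adjusted p of 0.302. Zdhhc9 (adjusted p = 0.0407) lost its call when each array was centred on its median (0.0630) and when the arrays were quantile normalised again (0.0559). Sprr1a (adjusted p = 0.0330) lost it with median centring (0.0517). In an ordinary test without moderation 12 of the 15 rises lost their call, among them Slc10a2 (0.0777), Jam3 (0.0891), Mmrn2 (0.0800), Nap1l2 (0.186), Apln (0.110) and Tslp (0.123). With any 1 array other than CREB3L1 replicate 3 left out, 7 to 9 of the 15 rises lost it, and Nap1l2 (0.106 or more), Sprr1a (0.0701 or more) and Zdhhc9 (0.0691 or more) did so each time. Apln and Zdhhc9 lie in a run of 55 neighbouring X-linked genes with a median difference of 0.19 relative to all genes.

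**Figure D2:**
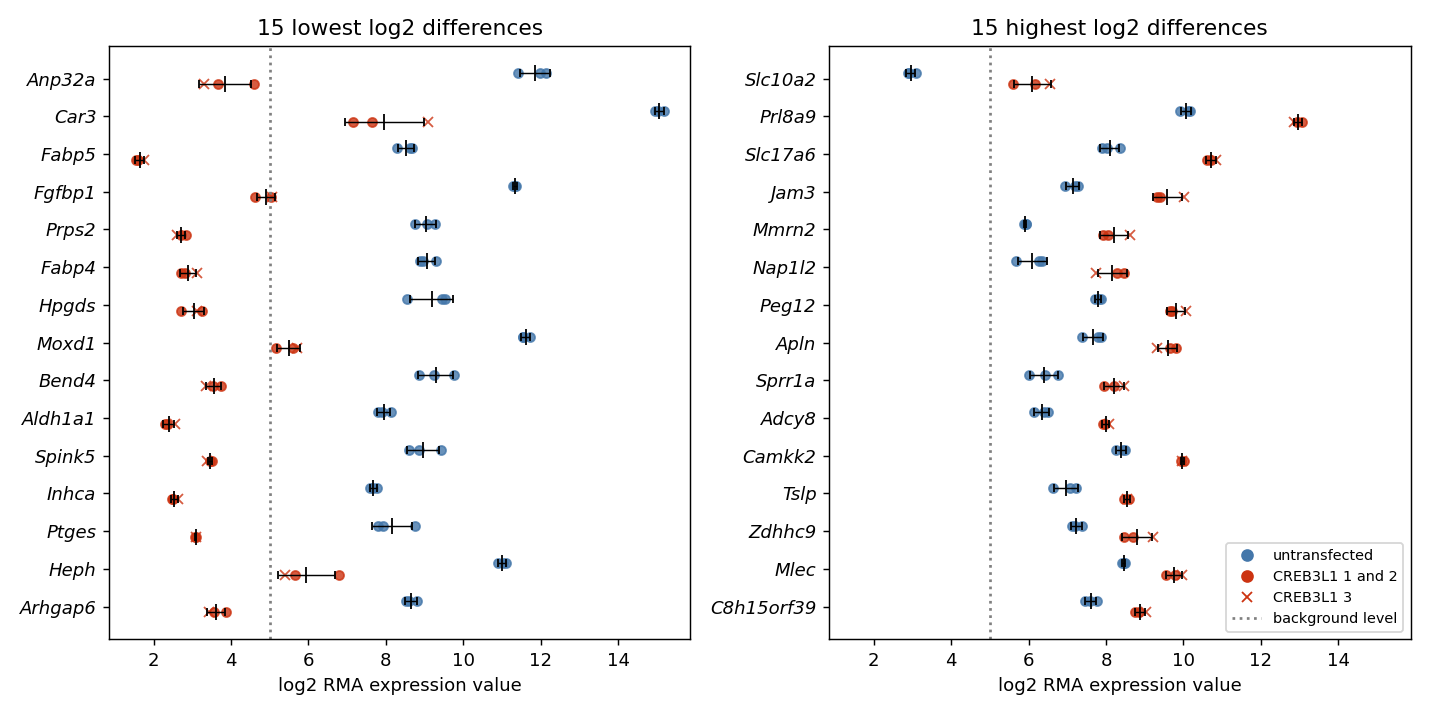
Log2 RMA expression values of the 15 genes with the lowest and the 15 with the highest log2 differences among those past an adjusted p of 0.05, values below background taken as they are, with each array as a point and mean ± SD as bars (n = 3 per group). Of the 15 falling genes, 12 have CREB3L1 means below the background level of 5.

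In all, 132 probe sets were higher and 299 lower in CREB3L1 cells at an adjusted p below 0.05, out of 31042 tested. Of these, 36 were higher and 162 lower by 2-fold or more, with the lower group alone below background for 3 and 63. Both groups were below it for a further 4 of the 36 and 15 of the 162, which count as 2-fold only with values taken as they are. Log2 differences of 4 or more, with values below background taken as they are, came to 1 higher and 28 lower, and several of the latter are shown only to be smaller folds against the background level. By gene, counting 1 probe set for each of 14217 genes, 82 rose and 216 fell. Leaving out CREB3L1 replicate 3 raised the counts to 479 higher and 756 lower, and these held all 132 and all 299 of the calls with 6 arrays. Of the calls by 2-fold with 6 arrays, 32 of the 36 and 154 of the 162 were also called by 2-fold without it. Leaving out any other array lowered both counts, to 28 to 44 higher and 116 to 135 lower. Of the other named genes past the test, 29 in all, 23 lost their call in the ordinary test, 8 with a mean-variance trend, 6 with quantile normalisation, 5 with median centring, 4 with robust eBayes, 17 to 21 without any 1 array other than CREB3L1 replicate 3, and 0 without that array. Of the 15 falls, Car3 and Heph lost it in the ordinary test (0.0680 and 0.0708) and without untransfected replicate 1 (0.0501 and 0.0518).

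Of the CREB3 family and the proteases that release its members, 10 genes were measured, of which 0 rose and 1 fell, and the count adjusted over the list alone was the same. The gene that fell was Mbtps2, the site-2 protease, from 11.34 ± 0.05 to 10.53 ± 0.05 (difference -0.81 ± 0.05, adjusted p = 0.00320). Mbtps2 belongs to the run of 95 X-linked genes named above. Camera gave this list an adjusted p of 0.455 (Down), while fry, which asks only whether members move one way on balance, gave 0.00460 (Down). Without CREB3L1 replicate 3, 2 members fell, the other being Atf6, a sensor of endoplasmic reticulum stress (-0.70, adjusted p = 0.0118, against -0.47 ± 0.21 and 0.588 with all arrays).

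Genes of the unfolded protein response did not move together. Of 27 measured members, Selenos rose by 0.30 ± 0.04 (adjusted p = 0.0472), Herpud1 fell by 0.93 ± 0.13 with an adjusted p just under the threshold, which rounds to 0.05, and 25 did not pass. Adjusted over the list alone, 4 rose and 3 fell. Both genes lost the call in several alternatives, Herpud1 with median centring (0.0573) and Selenos with quantile normalisation (0.0970). Camera gave an adjusted p of 0.754 in the direction Up, opposite in sign to the list's median (-0.06) and mean (-0.07). Without CREB3L1 replicate 3, 3 members rose, 2 fell and the median was 0.13.

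Secretory pathway transport genes lay slightly higher as a group than other genes (camera adjusted p = 0.00928, median 0.04, mean 0.12). The adjusted p was 0.223 with an estimated correlation. None of the 38 measured members passed the test with 6 arrays, while 2 rose when adjusted over the list alone. The COPII coat genes Sar1a and Sec24d had the smallest p, with differences of 0.31 ± 0.05 (adjusted p = 0.0616) and 0.95 ± 0.15 (adjusted p = 0.0624). Without CREB3L1 replicate 3 both passed the test (0.0224 and 0.00722) and 3 members rose. With dim probe sets left out, the list's adjusted p was 0.0519.

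Cholesterol synthesis genes lay higher too (camera adjusted p = 0.0288, and adjusted p = 0.278 with an estimated correlation). Of 18 measured members 2 rose and 0 fell, and 4 rose when adjusted over the list alone. Insig1, which holds back the sterol-sensing machinery, rose by 0.50 ± 0.05 (adjusted p = 0.0178) and the demethylase gene Cyp51 by 0.41 ± 0.05 (adjusted p = 0.0244), with 0.22 ± 0.10 on a second Cyp51 probe set (adjusted p = 0.663). With a mean-variance trend both calls were lost (0.123 for Insig1 and 0.0753 for Cyp51). The list's median was 0.10. Without CREB3L1 replicate 3, 5 rose and 1 fell, and the list's call was lost without CREB3L1 replicate 2 (0.126), with dim probe sets left out (0.130) and with the mean of all probe sets of a gene (0.0901).

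The amino acid response, genes driven by the transcription factor ATF4, had the lowest median difference of all lists, -0.59 over 20 measured members (camera adjusted p = 1.45e-13, adjusted p = 0.223 with an estimated correlation). Its mean was -0.78. Of these 4 fell and 0 rose, 13 fell when adjusted over the list alone, and 13 fell over all probe sets without CREB3L1 replicate 3. The cystine transporter gene Slc7a11 fell by 1.32 ± 0.06 (adjusted p = 0.00191). Chac1, whose product degrades glutathione, fell by 1.19 ± 0.10 (adjusted p = 0.00884), the amino acid transporter gene Slc7a5 by 0.57 ± 0.06 (adjusted p = 0.0170) and Aldh18a1, which serves proline synthesis, by 0.52 ± 0.05 (adjusted p = 0.0127). The Aldh18a1 call was lost with a mean-variance trend (0.0663).

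Hypoxia and glycolysis genes lay lower (camera adjusted p = 0.00413, adjusted p = 0.385 with an estimated correlation). Of 23 measured members 4 fell and 0 rose, and 5 fell when adjusted over the list alone. Ndrg1 fell by 0.87 ± 0.12 (adjusted p = 0.0481), Ankrd37 by 0.71 ± 0.09 (adjusted p = 0.0321) and the mitophagy receptor gene Bnip3 by 0.67 ± 0.09 (adjusted p = 0.0407). Pfkfb3, which encodes an activator of glycolytic flux, was at least 1.21-fold lower (adjusted p = 0.0134). The list's median was -0.13. With quantile normalisation the calls of Ndrg1 (0.0907) and Ankrd37 (0.165) were lost, and with a mean-variance trend that of Ankrd37 (0.0742). A second Ndrg1 probe set gave -1.76 ± 0.55 (adjusted p = 0.340). The other Pfkfb3 probe sets, 2 in number, lay below background in both groups.

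The lists on angiogenesis and on invasion and metastasis were drawn up knowing that the study's published account concerns those themes, so they are not fully independent of it. Of 40 measured angiogenesis genes 1 rose and 4 fell, and 3 rose and 5 fell when adjusted over the list alone. Besides Fgfbp1, the growth factor gene Vegfa fell by 0.87 ± 0.05 from 11.73 ± 0.05 (adjusted p = 0.00404), and the co-receptor gene Nrp1 by 1.33 ± 0.16 (adjusted p = 0.0310). Their second probe sets gave -0.85 ± 0.28 for Vegfa and -1.89 ± 0.43 for Nrp1, there with the CREB3L1 mean below background, without passing the test (adjusted p = 0.378 and 0.166). Vegfb passed the test with -1.06 ± 0.05 while below background in both groups. The member that rose was the chemokine gene Cxcl1, by 0.75 ± 0.08 (adjusted p = 0.0190). Camera did not call the list (adjusted p = 0.455, median -0.01, mean -0.21), and fry gave an adjusted p of 0.00824.

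Invasion and metastasis genes lay lower by camera (adjusted p = 0.0300, adjusted p = 0.736 with an estimated correlation), with a median of -0.06. None of the 41 measured members passed the test, and 2 fell when adjusted over the list alone. The smallest p belonged to the collagenase gene Mmp13, at -1.20 ± 0.18 (adjusted p = 0.0592) and below background in both groups, and to the protease inhibitor gene Timp2, at -0.61 ± 0.10 (adjusted p = 0.0657). Without CREB3L1 replicate 3 the list was not called (adjusted p = 0.195) and 4 members fell. The call was lost too with dim probe sets left out (0.0529), with array weights (0.270) and with fry (0.258).

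Collagen and extracellular matrix genes lay lower (camera adjusted p = 0.00526, adjusted p = 0.385 with an estimated correlation). Of 35 measured members 3 fell and 1 rose, and 8 fell and 2 rose when adjusted over the list alone. Col18a1, whose collagen yields endostatin, was at least 2.25-fold lower (adjusted p = 0.00101) and Col6a3 at least 2.33-fold lower (adjusted p = 0.0400), while a second Col6a3 probe set lay below background in both groups (0.02). The Col6a3 call was lost with quantile normalisation (0.0532). Fn1, the fibronectin gene, fell by 0.36 ± 0.05 from 14.20 ± 0.07, with an adjusted p of 0.0491 that was 0.107 after median centring. Loxl1 passed the test with 1.10 ± 0.13 while both groups lay below background. The median was -0.12, and -0.03 without CREB3L1 replicate 3, where 2 members rose and 7 fell.

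S phase genes lay higher as a group (camera adjusted p = 5.59e-04, adjusted p = 0.223 with an estimated correlation), by a median of 0.13 over 28 measured members. None passed the test, nor did any when adjusted over the list alone. Without CREB3L1 replicate 3, 0 members rose and 1 fell, while camera still called the list Up (adjusted p = 0.0178). Fen1 and Pola1, genes of DNA replication, gave 0.18 ± 0.04 and 0.30 ± 0.07 (adjusted p = 0.125 and 0.157). Pola1 lies near the Apoo end of the run of 95 X-linked genes, where the fall did not hold. It lay higher while the median of that run was -0.44. Among 28 G2/M genes 0 passed, also over the list alone, and camera gave an adjusted p of 0.568 in the direction Up with a median of 0.02 and a mean of -0.03, and an adjusted p of 0.0490 with array weights. Prc1 and Mki67 gave 0.16 ± 0.04 and 0.27 ± 0.07 (adjusted p = 0.197 and 0.224). Of 18 genes for p53 targets and cell death, the survival gene Bcl2l1 fell by 0.52 ± 0.06 (adjusted p = 0.0209) on the 1 of its 3 probe sets above background, and 0 rose. The Bcl2l1 call was lost with a mean-variance trend (0.140) and with the mean of its probe sets (0.138). The list had 2 rising and 2 falling members when adjusted over the list alone. Without CREB3L1 replicate 3, 2 rose and 2 fell over all probe sets. Camera gave that list an adjusted p of 0.608 in the direction Up, with a median of 0.03 and a mean of -0.09.

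Cytokine and signalling genes went both ways. In the list on NF-kB and cytokines, 3 of 25 measured members rose and 2 fell, and 4 rose and 6 fell when adjusted over the list alone. Tnfaip3 and Nfkb1, genes of the NF-kB circuit itself, rose by 1.10 ± 0.08 and 0.51 ± 0.04 (adjusted p = 0.00660 and 0.00637, that of Nfkb1 being 0.0765 with a mean-variance trend), while the chemokine gene Cxcl3 fell by 1.43 ± 0.15 (adjusted p = 0.0189), with 2 further probe sets past the test and 2 below background in both groups. Camera gave an adjusted p of 0.947. In the interferon response list, 1 of 25 rose and 1 fell, with 3 and 2 when adjusted over the list alone and a camera adjusted p of 0.608. Without CREB3L1 replicate 3, 2 of that list rose and 3 fell over all probe sets. The transcription factor gene Irf7 rose by 1.17 ± 0.17 (adjusted p = 0.0480, and 0.0602 with quantile normalisation), and Oasl was at least 2.51-fold lower (adjusted p = 0.0109). Of 18 TGF-beta response genes the activin subunit gene Inhba rose by 0.75 ± 0.06 (adjusted p = 0.00817) and 0 fell, with 2 rising and 2 falling over the list alone (camera adjusted p = 0.947). Of 17 mesenchymal transition genes, Fn1 fell and no other member passed, likewise over the list alone (camera adjusted p = 0.541).

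Most markers of cell types were below background. Of 24 luminal epithelial markers 2 were above background and 0 passed the test. Camera gave that list an adjusted p of 0.947 in the direction Up, with a median of -0.01 and a mean of 0.01, and Krt7 and Rab25 gave 0.30 ± 0.21 and 0.06 ± 0.03 from levels below background. Of 15 basal and myoepithelial markers 8 were above background and 0 passed (camera adjusted p = 0.746). Krt14 was at 15.25 ± 0.13 and 15.08 ± 0.14, and Krt15 was below background in both groups (-0.10 ± 0.04). Of 12 fibroblast markers 2 were above background and 0 passed (camera adjusted p = 0.754), with Col3a1 at 14.53 ± 0.07 and 14.72 ± 0.14 and Fbn1 at 8.14 ± 0.45 and 6.64 ± 1.25. No endothelial marker of 9, among them Tek (-0.17 ± 0.07) and Tie1 (-0.07 ± 0.05), was above background or passed (camera adjusted p = 0.531). Of 12 leukocyte markers 2 were above background and 0 passed (camera adjusted p = 0.568), with Cd14 at 11.06 ± 0.19 and 10.77 ± 0.24 and Laptm5 below background at 3.12 ± 0.50 and 2.12 ± 0.02. None of these lists had a member past the test when adjusted over the list alone.

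Of 8 adipocyte markers, Fabp4 and Pparg were above background, and both fell, also over the list alone. Pparg, the nuclear receptor of fat cell differentiation, fell by 1.47 ± 0.10 from 9.71 ± 0.16 (adjusted p = 0.00490). Camera called the list (adjusted p = 0.0110, adjusted p = 0.497 with an estimated correlation), with a median of -0.02 and a mean of -0.97.

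Among 10 housekeeping genes 0 passed the test and 2 rose when adjusted over the list alone. Hprt1 gave 0.44 ± 0.07 (adjusted p = 0.0763) and Tfrc, the transferrin receptor gene, 0.66 ± 0.12 (adjusted p = 0.0998). Hprt1 lies in the run of 55 X-linked genes. Camera called the list Up (adjusted p = 0.0335, adjusted p = 0.385 with an estimated correlation, median 0.06), and the call was lost with quantile normalisation (0.329), median centring (0.0643), dim probe sets left out (0.142), the mean of all probe sets of a gene (0.384) and fry (0.0857). It was lost as well without untransfected replicate 2 (0.143), CREB3L1 replicate 2 (0.0789) or CREB3L1 replicate 3 (0.105). Of 14 ribosomal protein genes 0 passed, also over the list alone, with Rpl4 at -0.10 ± 0.07 and Rps3 at -0.17 ± 0.13 (camera adjusted p = 0.608 in the direction Up, median 0.02, mean 0.03), a direction that turned with quantile normalisation. The 3' control probe sets of Gapdh and beta-actin differed by -0.02 each, at 15.64 ± 0.06 and 15.63 ± 0.04 and at 15.41 ± 0.02 and 15.39 ± 0.21.

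**Figure D3:**
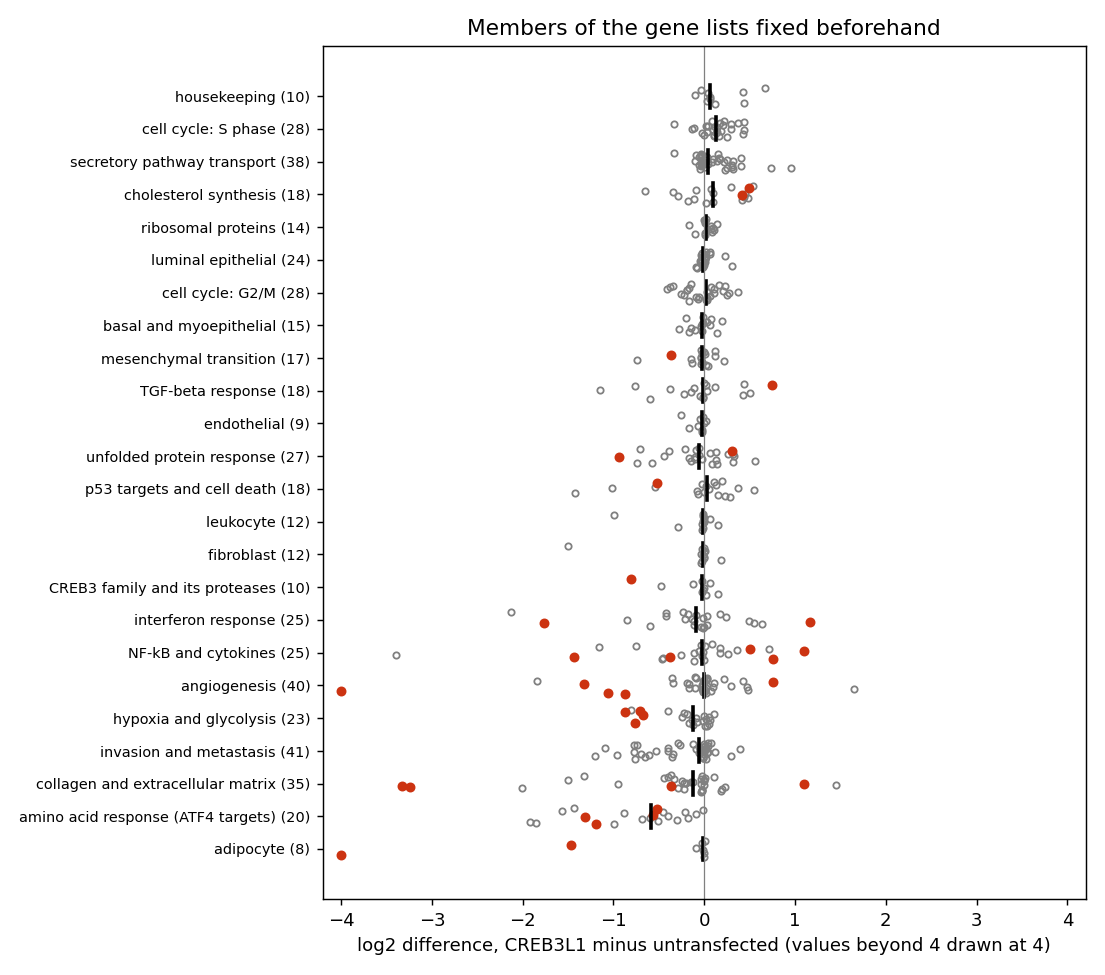
Log2 difference, CREB3L1 minus untransfected, of every measured member of the 24 gene lists, with members past an adjusted p of 0.05 filled and the median of each list as a bar (number measured in brackets, values beyond 4 drawn at 4). The median of the amino acid response list lies lowest, at -0.59.

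Across the lists, camera called 9 of 24 with its preset correlation and 0 with an estimated one, while fry called 9. Over single probe sets, 2999 (9.66%) had an unadjusted p below 0.05.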

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

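The test here was chosen only after its result was seen. A control probe set for 5S ribosomal RNA, outside the 31042 probe sets compared, was higher in every CREB3L1 array (6.87, 7.82 and 6.63) than in every untransfected array (5.15, 5.37 and 4.62). The difference in mean log2 value was 2.06 (two-sided exact permutation p = 0.1, the smallest that 3 arrays against 3 can give). It was picked as the control that differed most among 57, and no explanation for it was tested.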

How the results depend on the processing

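The array weights were chosen only after the result was seen, and the other tests here were planned. No paired analysis was run because the labels give no replicate numbers shared between the groups. In deposit order, the 3' minus 5' gap of dap was 3.38, 2.37 and 4.48 in untransfected arrays. In CREB3L1 arrays it was 3.44, 2.33 and 7.31. A pairing by that order was not tested. The direction of the main counts, more lower than higher, held in every alternative. Leaving out 1 array at a time gave 28 to 479 probe sets higher, 116 to 756 lower, 11 to 56 higher by 2-fold and 96 to 220 lower by 2-fold. The highest value of each came without CREB3L1 replicate 3, and each other array, left out, lowered the 4 counts. A mean-variance trend gave 79 higher. The ordinary test without moderation gave 9 higher and 65 lower, and 4 and 53 by 2-fold. Array weights gave 600 higher and 952 lower, and 56 higher by 2-fold. Camera called 7 to 9 lists with 1 array left out, 5 with dim probe sets left out and 0 with an estimated correlation. The cause of these moves was not tested.

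Of 1125 alternative values for 81 named genes, 901 kept direction and side of the threshold, 204 (38 genes) lost the call, 20 (10 genes) gained it and 0 turned. Lists that changed direction were not called either way, and their adjusted p-values were as follows. Quantile normalisation gave 0.920 for the unfolded protein response, 0.912 for luminal markers and 0.814 for ribosomal proteins. Leaving out dim probe sets gave 0.946 for NF-kB and 0.695 for TGF-beta. Array weights gave 0.473 for NF-kB, 0.958 for TGF-beta and 0.875 for interferon, luminal, basal and ribosomal lists. The mean of all probe sets gave 0.993 for NF-kB, TGF-beta and basal lists. Fry gave 0.9496 for p53, 0.712 for NF-kB, 0.640 for TGF-beta and 0.914 for luminal. With 1 array left out the ranges were 0.595 to 0.992 (NF-kB), 0.848 to 0.998 (TGF-beta), 0.629 to 0.840 (luminal), 0.175 to 0.848 (ribosomal), 0.0821 to 0.992 (unfolded protein response), 0.410 to 0.947 (interferon), 0.536 to 0.910 (basal), 0.490 to 0.998 (fibroblast) and 0.328 to 0.947 (endothelial).

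The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real grouping gave 132, 299, 36 and 162 probe sets in the 4 counts, each as large in 1 split, against 0 as the highest of the others. Camera at its preset correlation called 9 lists in the real grouping. It called 1 to 6 lists in each of the other splits, where 0 probe sets passed. Robust eBayes was not run for the list tests, since camera has no such option. Creb3l1 and the endothelial list have no value with dim probe sets left out. Signal over background limits the folds of the 66 lower and 4 higher probe sets whose other group was below it. A further 21 lower and 6 higher probe sets were below it in both groups.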

Other observations

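The tests of the gene groups, of CREB3L1 replicate 3 and of the X chromosome were chosen only after the result was seen. The test of fat-cell markers was recorded as fixed before, but its rule sets Fabp4 apart, so it may not be independent of the falls. Of 19 measured genes around prostaglandins, a group put together after the falls of some members were seen and given no test as a group, 3 fell and 0 rose. Besides Hpgds and Ptges, the prostaglandin-degrading dehydrogenase gene Hpgd fell by 3.62 ± 0.07 (n = 3 per group, limma adjusted p = 8.13e-05), while the cyclooxygenase gene Ptgs2 was at 15.79 ± 0.08 and 15.82 ± 0.30. Of 11 genes of the insulin-like growth factor axis 3 fell and 0 rose: the clearance receptor gene Igf2r by 1.30 ± 0.06, Igfbp6 by 1.63 ± 0.09 (adjusted p = 0.00148 and 0.00346), and Igfbp7, which was at least 6.68-fold lower (adjusted p = 0.0202). Without CREB3L1 replicate 3, 1 gene rose, Igf1r (0.54, adjusted p = 0.00865, against 0.45 ± 0.08 and 0.102 with all arrays).

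Of 15 genes of fatty acid handling 3 fell, Fabp5, Fabp4 and Pparg, and 0 rose, with Fasn at 0.51 ± 0.13 (adjusted p = 0.218). Without CREB3L1 replicate 3, 4 fell, the further one being Plin2 (-0.58, adjusted p = 0.0149, against -0.76 ± 0.17 and 0.155 with all arrays). Of 12 carbonic anhydrase genes 2 fell, Car3 and Car5b (by 1.03 ± 0.08, adjusted p = 0.00806), and 0 rose. Car5b lies in the run of 95 X-linked genes. Above background were only 2 of the 12 carbonic anhydrase genes, 11 of the 15 of fatty acid handling and 3 of the 9 of bone and cartilage matrix. The same held for 10 of the 19 prostaglandin genes and 4 of the 11 of the insulin-like growth factor axis. Of 9 genes of bone and cartilage matrix 0 passed, and Sparc gave 1.45 ± 0.32 (adjusted p = 0.162), or 1.81 without CREB3L1 replicate 3 (0.00227), where Spp1 fell (-0.47, adjusted p = 0.0369). Among probe sets with no listed gene, 1387029_at was at least 62.7-fold lower (adjusted p = 6.37e-05) and 1385868_at at least 16.4-fold higher, from 2.15 ± 0.07 to 9.03 ± 0.64 (adjusted p = 0.00191), the only called probe set that rose by 16-fold or more.

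CREB3L1 replicate 3 differed from the other arrays mostly in probe sets of genes whose other probe sets held. Of the 361 probe sets with 1 gene symbol that fell by over 2 on it, 303 had another detected probe set of the gene, and in 85.15% of those cases one fell by under 0.5. Probe set positions were not used and no comparison share was computed, so this alone does not point to the 3' end. With the 5' gaps of the control probe sets, loss of signal far from the 3' end of the labelled target is a candidate explanation. It would not explain the 63 probe sets that rose by over 2. The spiked-in dap RNA lost signal too, at its 5' probe set (2.08 against 4.67 to 7.56) but not its 3' probe set (9.38 against 9.16 to 9.89), which argues against breakage of the cellular RNA alone before the spike. A mislabelled untransfected sample is argued against by 85.87% of the 276 probe sets called by 2-fold without this array lying on the CREB3L1 side. The hybridisation controls had a median of 12.79 here and 10.52 to 10.74 elsewhere, and what lowered the 5' signal stays open, with no biological explanation tested.

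A run of neighbouring genes on the X chromosome lay lower, from Zfp182 to Apoo in the GRCr8 order, with 95 genes, 19 of them called lower and 1 higher. The fall did not hold up to Apoo. Near that end Tbl1x, Prkx, Tab3 and Pola1 were at 0.45, 0.37, 0.45 and 0.29 relative to all genes, and Ptges3l1 and Gk at -0.50 and -0.48. In the pair left out of the search, CREB3L1 replicate 3 and untransfected replicate 3, 77.89% of the run's genes were lower. That argues against noise of the searched arrays, but it rests on 1 pair that holds the array with lost 5' signal. The run was found in 4 arrays that do not include CREB3L1 replicate 3, so the lost 5' signal of that array did not enter the search. The median of -0.40 without that array reuses those 4 arrays and adds only untransfected replicate 3, so it is no separate test. The permutation p was 0.000999, the smallest that 1000 orders can give, as it was for 55 X-linked genes from Nxt2 to Xlr5c (median 0.19) and 32 genes on chromosome 12 from Brca2 to Rnf6 (median 0.32), and 0.0220 and 0.0210 for 43 genes each from Daglb to Mblac1 and from Crcp to Mlxip, with 77.19% of all 285 genes of chromosome 12 higher. The permutation p rests on the searched arrays alone. In the pair left out, 70.91%, 81.25%, 76.74% and 67.44% of genes went the same way in the runs from Nxt2, Brca2, Daglb and Crcp. Noise is thus less well argued against for the runs from Nxt2 and Crcp. Other chromosomes were skewed too, with 65.12% of 929 genes higher on chromosome 1. On chromosomes 18, 13 and 4, 35.96%, 37.38% and 38.77% were higher, and these skews were not tested. A difference between the cell populations in DNA copy number or in silencing of a chromosome part may underlie the median of -0.4429 in the run from Zfp182 to Apoo, but DNA was not measured. An action of CREB3L1 on the genes of that run cannot be told apart from such a difference. Prps2, Arhgap6, Mbtps2 and Car5b lie in this run, at -6.32, -5.04, -0.81 and -1.03 relative to all genes. Msl3, between Arhgap6 and Prps2 in the gene order, was at -0.47. A shift as large as the run's median would thus account for little of the falls of Prps2 and Arhgap6.

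Of the 15 genes with the lowest log2 differences, 12 were below background in CREB3L1 cells, in part because such genes are favoured by the ranking. Loss of fat-cell-like cells from the culture would remove their markers together. Of the 8 adipocyte markers, only 1 besides Fabp4, namely Pparg, was above background in untransfected cells, and both fell. A marker below background cannot show a fall, so the test does not decide on such a loss. Also open are the transfection itself and a difference between the cell populations compared that did not come from CREB3L1, as might arise if the transfected cells grew from few cells. The labels do not say how they were selected, and neither was tested.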
